A study of Mus musculus with 140 samples.

How the data were processed

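ATAC-seq counts of 63 libraries were analysed: Treg and CD4+Foxp3- cells from B16 or MC38 tumors and from non-draining lymph nodes at days 8, 12, 16 and 20, from C57BL/6 Foxp3Cre-YFP mice given 125000 B16 or 250000 MC38 cells. The deposited values are counts per peak, 1 table for each tumor and cell type (4 tables), whole numbers whose totals differ between libraries. Per the submitters' processing notes BWA, MACS2 2.1.2 and featureCounts were used with build mm10. Their order, the filters and the way peaks were merged are not given in the sources used here. Of 140 deposited columns, 77 in 2 further tables were not used here, since their names do not give a group. The column names of the 4 tables used give tissue and day, and most give a serial number, but none gives the replicate number of the sample labels, so replicates were called a and b in column order.

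The tables hold 98392 (B16 Treg), 68948 (MC38 Treg), 65077 (B16 CD4+Foxp3-) and 82649 peaks (MC38 CD4+Foxp3-). Each peak was given the protein-coding gene whose body it overlaps, or otherwise the nearest within 100 kb, among 21900 genes of assembly GRCm38.p6. This assigned 92.88%, 93.33%, 93.30% and 92.26% of peaks. The gene table has no strand, so a peak was described as within 1 kb of a gene end rather than as a promoter. Median counts in peaks per library were 1375390, 1658930, 1401532 and 1743080, and the biological coefficient of variation was 0.195, 0.220, 0.160 and 0.217, in the same order.

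Each table was analysed alone with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10 and a minimum total of 15, TMM scaling, a robust quasi-likelihood fit and Benjamini-Hochberg correction over all peaks tested. Peaks were called at an adjusted p under 0.05, and counted also at an absolute log2 fold of 1 or more. TIL and LN were compared in a model of day plus tissue. Differences among days within a tissue, and the tissue by day interaction, were F tests in a model with 1 mean per tissue and day. Their direction is day 20 minus day 8. TIL and LN were also compared within each day in the model with 1 mean per tissue and day, whose spread comes from all libraries. The single TIL library of day 12 in B16 CD4+Foxp3- cells was assumed to vary like the other groups. Mean log2 CPM values and the principal components used a prior count of 2, which does not enter the fitted log2 folds. Where the counts of a named peak summed to 3 or fewer over a tissue, the ratio of counts per TMM-scaled depth is given with an exact 95% counting interval in place of a fitted fold.

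Before the data were examined, 17 gene lists with 155 genes, the tests and the rule for naming genes were fixed. All peaks assigned to a list's genes were tested as a set with camera (limma 3.58.1), with the preset correlation of 0.01 and with an estimated correlation, if at least 3 were tested. Beside each list stands its number of called peaks, with p adjusted over all peaks and over the list alone. Genes named in the text are list genes, given with their peak of lowest p, or the genes of the 5 opened and 5 closed peaks of largest change among called peaks with above-median signal whose tissues do not overlap. The strongest peak of a gene means its peak of lowest p, not that of largest change. For F tests the 5 lowest p per direction were used. Not every gene that this rule allows is named, and genes picked in another way are marked as such. Peaks of 2 tables were matched one to one by best mutual overlap and compared by odds ratio and by Spearman correlation.

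Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, loess offsets (span 0.3), no filter, DESeq2 1.42.0, each library left out in turn, a reciprocal overlap of 50%, an absolute log2 fold of 1 for the overlap, and the estimated correlation for lists. Chosen after seeing the data were the share of counts on unplaced scaffolds as a covariate, MC38 without TIL day 8 b and TIL day 12 b, list peaks within 1 kb of a gene end, and leaving out each library with the peaks tested held fixed. The last was added because filtering anew lets more peaks in when a group is left with 1 library. TIL and LN labels were also reassigned in 20 random splits of each table's libraries, 21 with the real one, of 6435 possible.

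The pipeline was tested on simulated data in which 200 peaks per comparison were changed. All other peaks were drawn without a difference, whereas 39.8% to 52.7% of real peaks were called between TIL and LN. The rates below therefore need not hold for the real TIL and LN comparison. Between TIL and LN it recovered 60%, 51%, 57% and 53% of 2-fold changes (B16 Treg, MC38 Treg, B16 CD4+Foxp3- and MC38 CD4+Foxp3-) and 91%, 86%, 89% and 87% of 4-fold changes. False calls were 14 of 165, 6 of 143, 11 of 157 and 6 of 146. For days within TIL it recovered 10%, 2%, 10% and 6% of 2-fold and 74%, 50%, 71% and 43% of 4-fold changes, with 22 of 106, 10 of 62, 6 of 87 and 8 of 57 calls false, above the nominal 5%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.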

Results

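Chromatin accessibility was measured by ATAC-seq in regulatory T cells (Treg) and in CD4+Foxp3- T cells from B16 and MC38 tumors (tumor-infiltrating lymphocytes, TIL) and from non-draining lymph nodes (LN) at days 8, 12, 16 and 20. Each tumor and cell type has its own count table. Every tissue and day has 2 libraries, called a and b here, except CD4+Foxp3- TIL of B16 at day 12, which has 1. Counts in peaks ranged from 550363 to 4816479 per library in B16 Treg (16 libraries), 757869 to 4005698 in MC38 Treg (16), 725419 to 3628807 in B16 CD4+Foxp3- cells (15) and 380166 to 2750444 in MC38 CD4+Foxp3- cells (16). The first principal component held 49.4%, 49.5%, 53.2% and 42.8% of the variance in that order and separated TIL from LN, except that TIL day 8 b and TIL day 12 b of MC38 lay near LN in both cell types. Changes named below between TIL and LN passed the edgeR test at an adjusted p under 0.05. Their sign and call held in every alternative checked, unless stated otherwise. For peaks marked as chosen after their values were seen, no alternative was checked. The labels do not state that replicate libraries came from separate animals, so the p-values may measure technical spread.

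**Figure D1:**
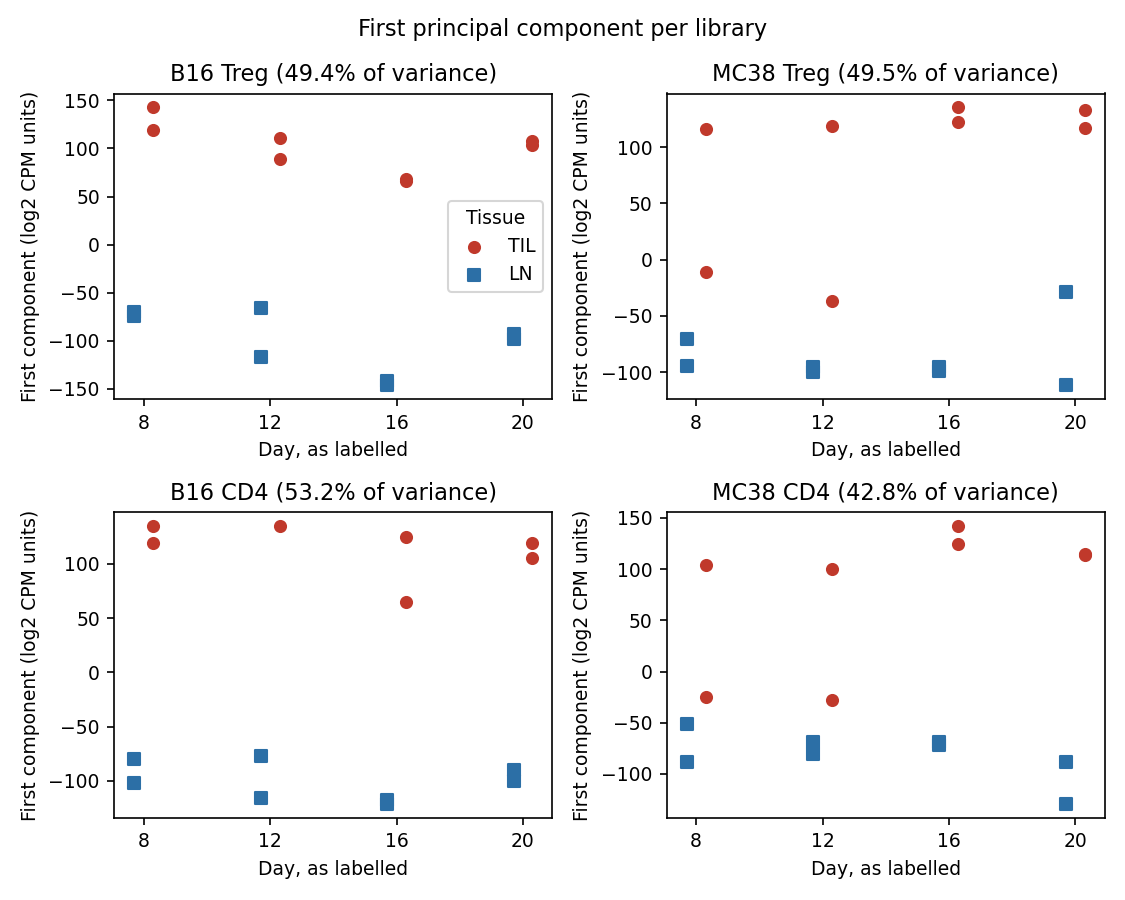
First principal component of log2 CPM of each library in each of the 4 tables, by tissue and day. Each dot is 1 library.

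The first comparison asks how Treg chromatin in a B16 tumor differs from Treg chromatin in a lymph node that does not drain it (8 TIL and 8 LN libraries). Single peaks of genes of the effector Treg list were more open in the tumor, although the list as a set was called only with a preset correlation (adjusted p = 2.21e-05 by camera) and had an adjusted p = 0.284 with an estimated correlation. The peak with the lowest p at Il10, the gene of an inhibitory cytokine, opened by 2.65 ± 0.16 (log2 ± SE), and 12 of the 12 tested peaks of this gene opened. Klrg1, a receptor of terminally differentiated effector cells, opened by 2.52 ± 0.17 with 13 of 14 peaks. Maf, a transcription factor that drives Il10, opened by 2.56 ± 0.25. Peaks of the costimulatory receptor gene Tnfrsf9 (1.98 ± 0.15, 8 opened and 4 closed of 14) and of the inhibitory receptor gene Tigit (3.58 ± 0.27, 11 opened and 2 closed of 18) also opened.

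Neither the tissue repair nor the type 1 list was called as a set in B16 Treg, but single peaks of their genes opened. Il1rl1, which encodes the IL-33 receptor ST2, opened by 4.47 ± 0.28 with 5 peaks opened and 2 closed of 7. Pparg, needed by Treg of adipose tissue, opened by 2.52 ± 0.33, and Rora by 1.42 ± 0.18 (10 opened and 5 closed of 21). Tbx21, which encodes T-bet, opened by 3.71 ± 0.26 in 3 of 3 peaks, and its targets Cxcr3 (2.20 ± 0.24) and Ifng (2.99 ± 0.25, 4 opened and 2 closed of 14) carried opened peaks as well. The chemokine gene Ccl5 opened by 4.14 ± 0.30. Runx3, a partner of T-bet, opened by 4.44 ± 0.39 (8 opened and 1 closed of 15 peaks). Gzmb, a granzyme gene, had its strongest peak opened (3.24 ± 0.28) but 3 of its 7 peaks closed against 1 opened. Havcr2, which encodes the inhibitory receptor TIM-3, opened by 2.0 ± 0.23, Irf1 by 3.86 ± 0.35 and the AP-1 gene Fosl2 by 3.87 ± 0.29.

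Single peaks of the naive and lymphoid homing list closed in B16 Treg, a list called with the preset correlation only (adjusted p = 0.284 with an estimated correlation). Satb1, a chromatin organizer needed early in Treg development, changed by -4.22 ± 0.29 and had 17 of 18 peaks closed and 0 opened. Dapl1, a marker of naive T cells, changed by -4.52 ± 0.36 with 11 of 11 peaks closed, and Bach2, a repressor of effector programs, by -4.33 ± 0.26 with 27 closed and 7 opened of 43. Of other lists, Gpr83, a receptor of resting Treg, changed by -3.74 ± 0.35, Bcl6 by -4.47 ± 0.54 and Eomes by -3.22 ± 0.41. Tox, a factor of exhausted T cells, closed as well: its peak of lowest p changed by -2.19 ± 0.19, and 19 of 30 peaks closed against 5 opened. Among peaks of above-median signal whose TIL and LN libraries did not overlap, the largest openings lay at Gm30733 (5.27 ± 0.29), Myo16 (5.13 ± 0.32), 2810004N23Rik (5.10 ± 0.30), Plxnc1 (4.97 ± 0.32) and the phosphatase gene Ptpre (4.96 ± 0.26). The largest closings lay at Cmss1 (-5.42 ± 0.26), Tdrd3 (-5.20 ± 0.31), 2210010C04Rik (-5.16 ± 0.34), Chl1 (-5.02 ± 0.31) and Syne1 (-4.76 ± 0.33).

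Of 44340 peaks tested in B16 Treg, 11040 opened and 12202 closed in TIL at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 52.4% of all tested. With an absolute log2 fold of 1 or more the counts were 5014 and 6806. Every TIL library lay above every LN library at 2392 opened peaks, and below at 3626 closed peaks, an order that chance gives at 0.0155% of peaks. Opened peaks lay within 1 kb of a gene end in 31.8% of cases, closed peaks in 16.9% and peaks not called in 41.1%.

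As sets, 3 of the lists fixed before the data were examined moved in B16 Treg by camera with its preset correlation. The effector Treg list opened (69 opened and 26 closed of 124 peaks, 69 and 26 adjusted over the list alone, adjusted p = 2.21e-05). The naive and lymphoid homing list closed (20 opened and 113 closed of 180 peaks, 22 and 113 over the list alone, adjusted p = 2.74e-07). The interferon list opened (12 opened and 3 closed of 26 peaks, 12 and 3 over the list alone, adjusted p = 0.0052). None of these 3 calls held when camera estimated the correlation between peaks: the adjusted p = 0.284 with an estimated correlation for each of them. The lists for core Treg genes (40 opened and 50 closed, 41 and 51 over the list alone, adjusted p = 0.597) and tissue repair (26 opened and 13 closed, 26 and 13 over the list alone, adjusted p = 0.079) were not called. Nor were inhibitory receptors (51 opened and 38 closed, 54 and 39 over the list alone, adjusted p = 0.501) and type 1 or cytotoxic genes (30 opened and 18 closed, 30 and 19 over the list alone, adjusted p = 0.229). Other helper lineages (4 opened and 11 closed, 4 and 11 over the list alone, adjusted p = 0.597) and the AP-1 and T cell receptor response (41 opened and 30 closed, 42 and 31 over the list alone, adjusted p = 0.229) did not pass. Hypoxia genes did not either (17 opened and 7 closed, 17 and 7 over the list alone, adjusted p = 0.26, with a median of -0.03 and a mean of 0.30 log2). The tissue repair list was called without LN day 12 b (0.0444), with loess scaling (0.0409) and with no filter (0.000836), and the AP-1 list opened (0.0335) and the core list lay lower (0.0276) with peaks within 1 kb of a gene end. None of these was called in those fits with an estimated correlation (adjusted p of 0.168 or more).

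The same question was asked of MC38 Treg (8 TIL and 8 LN libraries). Again Il10 opened (2.40 ± 0.28, 11 of 12 peaks), as did Klrg1 (2.08 ± 0.29, 14 of 15 peaks), Maf (2.36 ± 0.39), Tnfrsf9 (1.59 ± 0.21, 8 opened and 2 closed of 14) and Tigit (3.20 ± 0.41, 6 and 1 of 19). Of the tissue repair list 33 of 74 peaks opened and 6 closed, and its call was lost (adjusted p = 0.289 with an estimated correlation). Among its genes Il1rl1 opened by 3.92 ± 0.50 with 6 peaks opened and 1 closed, Rora by 2.11 ± 0.26 with 16 opened and 3 closed of 31, and Pparg by 2.93 ± 0.50 with 3 of 3. The strongest peak of Nfil3, a transcription factor gene of effector Treg in tissues, held 101 counts over the TIL libraries and 1 over the LN libraries, a ratio per depth of 90.1 (95% counting interval 15.8 to 3592). That of Tbx21 held 81 counts over the TIL libraries and 3 over the LN libraries, a ratio per depth of 24.1 (95% counting interval 7.95 to 119), and all 4 tested peaks of the gene opened. Havcr2 opened by 2.1 ± 0.30, Ccl5 by 3.29 ± 0.49 and Irf1 by 1.23 ± 0.20.

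Of the peaks of the AP-1 and T cell receptor list in MC38 Treg, 52 opened and 20 closed, and its call was lost (adjusted p = 0.289 with an estimated correlation). Fosb opened by 3.11 ± 0.24 (9 of 11 peaks), Fos by 2.64 ± 0.42 (8 of 11) and Fosl2 by 4.56 ± 0.53 (4 of 4). Junb (4 of 4 opened), Jund (4 of 5), Fosl1 (1 of 1) and Batf3 (2 of 3) had no closed peak either, whereas Jun changed by -1.74 ± 0.23 with 6 closed and 1 opened of 12. Satb1 (-2.78 ± 0.40, 14 of 20 peaks closed), Dapl1 (-1.94 ± 0.38, 10 of 11), Gpr83 (-2.47 ± 0.43), Bcl6 (-2.71 ± 0.48, 5 closed and 2 opened of 11) and Tox (-1.66 ± 0.25, 20 closed and 3 opened of 32) closed at their peaks of lowest p. Among the largest openings at peaks of above-median signal were those of Ccdc148 (3.81 ± 0.47), Tspan32 (3.68 ± 0.34), the interferon receptor gene Ifnar2 (3.62 ± 0.42) and Atp10a (3.54 ± 0.53), beside Fosl2 itself. The largest closings were at Cyria (-3.12 ± 0.37), Chl1 (-2.93 ± 0.39), the chromatin remodeler gene Chd7 (-2.82 ± 0.57), Scfd2 (-2.81 ± 0.35) and 4930453N24Rik (-2.80 ± 0.38).

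Of 49458 peaks tested in MC38 Treg, 10678 opened and 10644 closed (43.1% of all tested), and 5239 and 6465 did so with an absolute log2 fold of 1 or more. TIL and LN libraries did not overlap at 965 opened and 1257 closed peaks, where chance gives 0.0155% of peaks. Opened, closed and uncalled peaks lay within 1 kb of a gene end in 31.4%, 11.6% and 36.1% of cases. By camera with the preset correlation, the effector Treg list opened (66 opened and 16 closed of 138 peaks, 66 and 16 over the list alone, adjusted p = 0.000371). So did the lists for tissue repair (33 opened and 6 closed of 74 peaks, 39 and 6, adjusted p = 1.87e-05) and AP-1 (52 opened and 20 closed of 125 peaks, 53 and 21, adjusted p = 0.0129). The naive and lymphoid homing list closed (19 opened and 90 closed of 204 peaks, 19 and 94, adjusted p = 6.57e-06). None of the 4 held: adjusted p = 0.371, 0.289, 0.289 and 0.466 with an estimated correlation, in the same order. The core Treg list was not called (41 opened and 39 closed, 42 and 39 over the list alone, adjusted p = 0.972), and lay lower by the test although its median of 0.02 and mean of 0.05 are above 0. With peaks within 1 kb of a gene end it passed, lower (0.0202, but adjusted p = 0.399 with an estimated correlation). Inhibitory receptors (35 opened and 35 closed, 35 and 35 over the list alone, adjusted p = 0.844) and type 1 and cytotoxic genes (27 opened and 21 closed, 29 and 24 over the list alone, adjusted p = 0.626) were not called. Other helper lineages did not pass (6 opened and 14 closed, 7 and 14 over the list alone, adjusted p = 0.582, median 0.0044 and mean -0.23). Hypoxia (16 opened and 4 closed, 15 and 3 over the list alone, adjusted p = 0.24) and interferon genes (15 opened and 3 closed, 16 and 3 over the list alone, adjusted p = 0.136) did not pass either.

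The next comparison asks how CD4+Foxp3- cells in B16 tumors differ from those in LN (7 TIL and 8 LN libraries). Peaks of the type 1 and cytotoxic list went both ways (44 opened and 26 closed of 91 peaks), and its call was lost (adjusted p = 0.327 with an estimated correlation). Tbx21 opened by 5.46 ± 0.35 in 5 of 5 peaks, Ifng by 4.75 ± 0.28 in 12 of 16, Cxcr3 by 5.19 ± 0.36, Ccl5 by 5.69 ± 0.39, Gzmb by 4.81 ± 0.42 (2 opened and 1 closed of 6) and the cytotoxic granule gene Nkg7 by 3.60 ± 0.26. Prf1, the perforin gene, instead had 4 of 4 peaks closed, and Eomes 5 closed and 1 opened of 7. Nkg7 belongs to the CD8 and NK list, which was not called. The strongest peak of Klrg1 held 206 counts over the TIL libraries and 1 over the LN libraries, a ratio per depth of 212 (95% counting interval 37.7 to 8424), and 7 of its 7 peaks opened. That of Il1rl1 held 146 counts over the TIL libraries and 2 over the LN libraries, a ratio per depth of 75.2 (95% counting interval 20.5 to 627).

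Il10 stood out in these cells. The largest opening at a peak of above-median signal lay 16114 bp from it on chromosome 1, 131003192 to 131003731. It held 364 counts over the TIL libraries and 3 over the LN libraries, a ratio per depth of 125 (95% counting interval 42.4 to 609). Maf opened by 3.79 ± 0.34, Rora by 4.55 ± 0.32 (8 opened and 5 closed of 18) and Havcr2 by 2.45 ± 0.32. Il17a, the gene of the lead Th17 cytokine, opened by 3.38 ± 0.16 in 3 of 3 peaks. At Il5, a type 2 cytokine gene, 4 of 4 peaks opened and the strongest held 74 counts over the TIL libraries and 1 over the LN libraries, a ratio per depth of 76.3 (95% counting interval 13.3 to 3052). Nfatc1, which relays calcium signals from the T cell receptor, opened by 4.31 ± 0.26 (7 opened and 4 closed of 24), Fosb by 3.74 ± 0.31, Fosl2 by 4.42 ± 0.39 and the interferon-induced gene Ifit3 by 3.41 ± 0.22. Other large openings lay at Ttc39c (6.28 ± 0.36), Rcsd1 (6.04 ± 0.34), Aplp2 (5.81 ± 0.37) and Gnptab (5.77 ± 0.26).

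Satb1 (-2.51 ± 0.23, 25 of 27 peaks closed) and Dapl1 (-2.37 ± 0.20, 13 closed and 1 opened of 16) closed in CD4+Foxp3- cells of B16 tumors. Il12rb2, a subunit of the IL-12 receptor, changed by -2.79 ± 0.26 with 7 closed and 1 opened of 9 peaks, although Tbx21 and Ifng opened. Tox (-1.17 ± 0.12, 21 closed and 3 opened of 27) and Jun (-0.69 ± 0.11, 7 of 10) closed too. Bach2 was mixed, with 23 closed and 9 opened peaks of 49, and its peak of lowest p opened (2.22 ± 0.13). At Ctla4 the peak of lowest p changed by -2.25 ± 0.21, yet 7 peaks opened against 3 closed. The largest closings lay at Cxadr (-3.85 ± 0.30), Slc4a4 (-3.66 ± 0.18), 1700016C15Rik (-3.59 ± 0.28), Adamts20 (-3.56 ± 0.26) and Fpr-rs4 (-3.52 ± 0.29).

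Of 49465 peaks tested in B16 CD4+Foxp3- cells, 12756 opened and 13288 closed (52.7%), 6102 and 8812 of them with an absolute log2 fold of 1 or more. The tissues did not overlap at 3761 opened and 4540 closed peaks, where chance gives 0.0311% of peaks. Opened, closed and uncalled peaks lay within 1 kb of a gene end in 33.6%, 12.1% and 36.9% of cases. The effector Treg list opened (64 opened and 17 closed of 103 peaks, 64 and 20 over the list alone, adjusted p = 2.93e-07 by camera with the preset correlation), and adjusted p = 0.0408 with an estimated correlation, a call kept in 8 of 15 fits that each left out 1 library (up to 0.0807). The lists for tissue repair (23 opened and 6 closed of 45 peaks, 23 and 6, adjusted p = 0.00484) and type 1 and cytotoxic genes (44 opened and 26 closed of 91 peaks, 45 and 26, adjusted p = 0.0395) opened. The AP-1 list opened (53 opened and 20 closed of 120 peaks, 54 and 21, adjusted p = 0.00524), and the naive list closed (38 opened and 111 closed of 224 peaks, 39 and 112, adjusted p = 0.00101). These 4 were lost: adjusted p = 0.0942, 0.327, 0.148 and 0.215 with an estimated correlation. The type 1 call also ended without LN day 8 b, LN day 12 a or TIL day 16 b, where its adjusted p reached 0.0542. Core Treg genes (48 opened and 37 closed, 49 and 39 over the list alone, adjusted p = 0.436) and inhibitory receptors (50 opened and 38 closed, 50 and 38 over the list alone, adjusted p = 0.28) were not called. Nor were other helper lineages (19 opened and 14 closed, 19 and 15 over the list alone, adjusted p = 0.348), hypoxia (17 opened and 10 closed, 17 and 10 over the list alone, adjusted p = 0.436) and interferon genes (12 opened and 5 closed, 12 and 5 over the list alone, adjusted p = 0.0993).

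CD4+Foxp3- cells of MC38 tumors were compared with LN in the same way (8 TIL and 8 LN libraries). The strongest Ifng peak held 114 counts over the TIL libraries and 1 over the LN libraries, a ratio per depth of 109 (95% counting interval 19.2 to 4351), and 8 of its 15 peaks opened. Tbx21 opened by 5.54 ± 0.57 in 5 of 5 peaks, Ccl5 by 4.42 ± 0.56, Nkg7 by 4.11 ± 0.60, Il10 by 3.76 ± 0.50 (10 of 11), Tigit by 3.92 ± 0.56 (7 opened and 4 closed of 14) and Il17a by 3.81 ± 0.69 (3 of 3). At Klrg1 the strongest peak held 132 counts over the TIL libraries and 2 over the LN libraries, a ratio per depth of 63.2 (95% counting interval 17.2 to 528). Il1rl1 (4.97 ± 0.60) and Rora (4.27 ± 0.51, 10 opened and 4 closed of 22) opened as in B16, and so did Ikzf2, which encodes Helios (3.82 ± 0.55, 7 and 1 of 16). The peak of lowest p at Fos held 114 counts over the TIL libraries and 2 over the LN libraries, a ratio per depth of 54.6 (95% counting interval 14.8 to 456), and 9 of 12 peaks opened. Fosb (3.76 ± 0.35), Fosl2 (1.30 ± 0.13), Batf3 (3.54 ± 0.71) and Irf1 (3.73 ± 0.67) opened.

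Satb1 (-1.56 ± 0.26, 18 of 31 peaks closed), Dapl1 (-1.98 ± 0.18, 10 of 14), Tox (-1.04 ± 0.17, 14 closed and 3 opened of 28) and Jun (-1.06 ± 0.16, 5 closed and 1 opened of 12) closed at their peaks of lowest p in these cells. The largest openings at peaks of above-median signal lay at Rcsd1 (6.17 ± 0.67), Tbx21, Ankrd44 (5.0 ± 0.70), 1700057G04Rik (4.94 ± 0.70) and Atxn1 (4.94 ± 0.52). The largest closings lay at Gtpbp4 (-2.57 ± 0.29), the antiproliferative gene Btg1 (-2.41 ± 0.22), Zfp677 (-2.41 ± 0.26), Dph6 (-2.39 ± 0.31) and Lancl1 (-2.38 ± 0.24). Of 49662 peaks tested, 10022 opened and 9763 closed (39.8%), 4740 and 5544 of them with an absolute log2 fold of 1 or more. The tissues did not overlap at 895 opened and 876 closed peaks, where chance gives 0.0155%. Opened, closed and uncalled peaks lay within 1 kb of a gene end in 35.2%, 9.53% and 34.7% of cases.

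Among the lists, effector Treg (58 opened and 13 closed of 108 peaks, 60 and 15 over the list alone, adjusted p = 9.53e-06 by camera with the preset correlation) and AP-1 genes (49 opened and 11 closed of 127 peaks, 50 and 11, adjusted p = 0.000148) opened in MC38 CD4+Foxp3- cells. Neither held: adjusted p = 0.377 and 0.0717 with an estimated correlation. Core Treg genes did not pass (34 opened and 26 closed, 34 and 26 over the list alone, adjusted p = 0.945), with a median of -0.02 and a mean of 0.34. Tissue repair (19 opened and 5 closed, 19 and 5 over the list alone, adjusted p = 0.0795) and inhibitory receptor genes (38 opened and 30 closed, 40 and 35 over the list alone, adjusted p = 0.68) were not called. Nor were naive and homing genes (44 opened and 67 closed, 44 and 69 over the list alone, adjusted p = 0.177) and type 1 and cytotoxic genes (35 opened and 17 closed, 38 and 19 over the list alone, adjusted p = 0.105). Other helper lineages (12 opened and 12 closed, 13 and 12 over the list alone, adjusted p = 0.945) lay lower by the test, with a median of 0.02 and a mean of 0.19. Hypoxia genes were not called (9 opened and 8 closed, 9 and 8 over the list alone, adjusted p = 0.718, median -0.09 and mean 0.13). Interferon genes were not called either (10 opened and 1 closed, 10 and 1 over the list alone, adjusted p = 0.069). Some of these results depended on single libraries or settings. Without TIL day 8 b, one of the libraries near LN, the tissue repair and interferon lists opened and the naive list closed (adjusted p = 0.0446 each). The tissue repair and interferon lists were also called without LN day 12 a (0.0447 each) or LN day 20 b (0.0369 each), and the interferon list without LN day 12 b (0.0442). Without TIL day 12 b, the other library near LN, both were called (0.0250 each). Without both of these TIL libraries the tissue repair (0.0168), naive (0.0447), type 1 (0.0348) and interferon lists (0.0348) were called. With no filter the tissue repair (0.00306), type 1 (0.00453) and interferon lists (0.0353) opened, and with peaks within 1 kb of a gene end the naive list closed (0.00029). None of these lists was called in those fits with an estimated correlation (adjusted p of 0.260 or more).

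**Figure D2:**
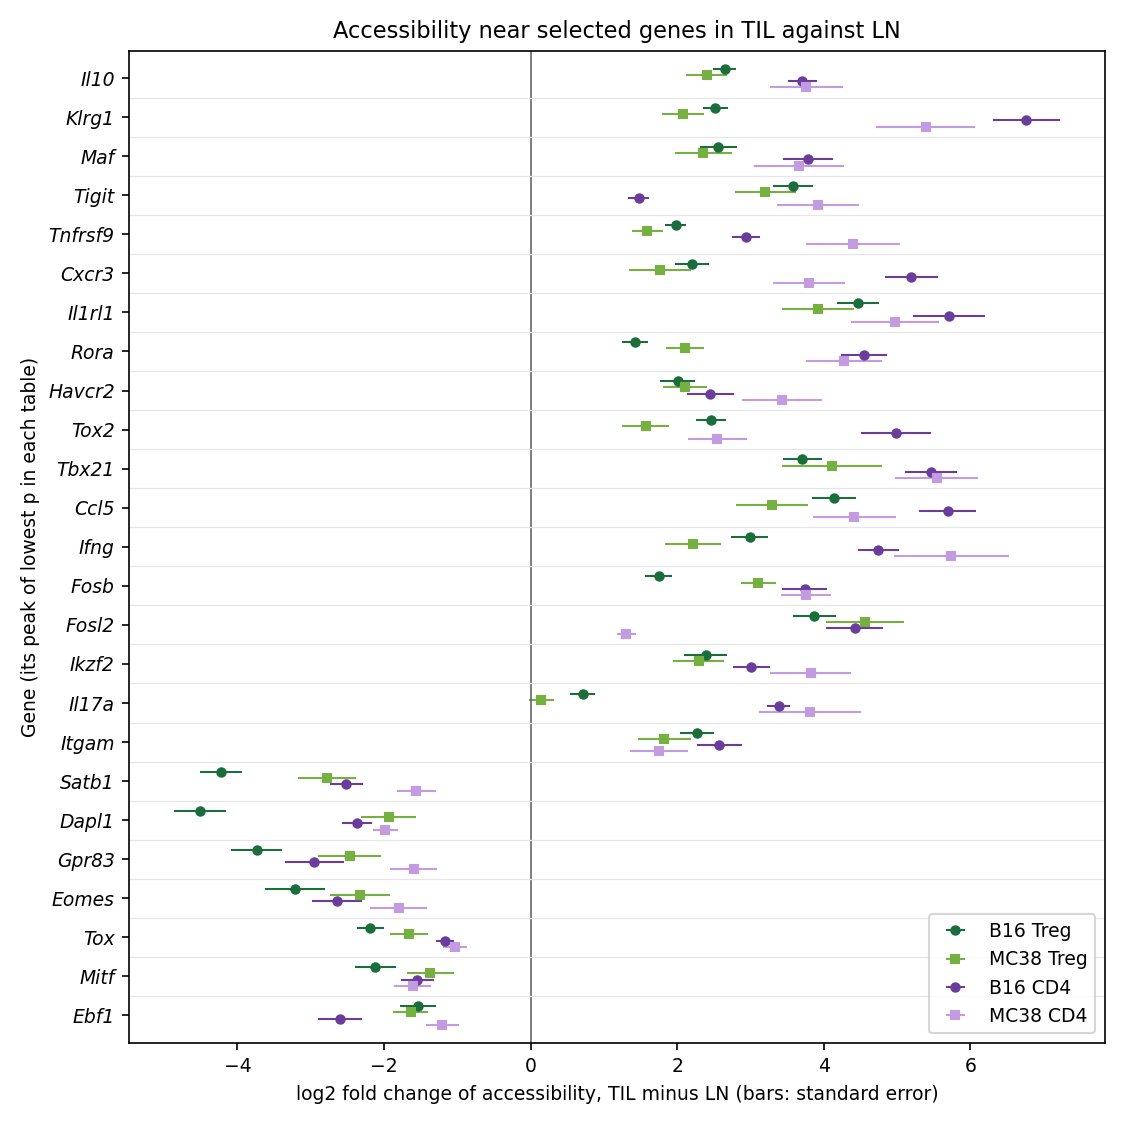
Log2 difference between TIL and LN at the peak of lowest p of 25 list genes in the 4 tables. Values are those of the edgeR fit, and values of peaks with few counts in 1 tissue are uncertain.

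Foxp3, which defines the Treg lineage, has 1 tested peak in each Treg table. In B16 Treg the peak on chromosome X, 7583912 to 7584386, differed by 0.07 ± 0.18 log2 between TIL (5.08 ± 0.51, mean log2 CPM ± SD) and LN (4.95 ± 0.45). In MC38 Treg the peak at 7583913 to 7584399 differed by 0.06 ± 0.16 (5.03 ± 0.38 in TIL and 4.93 ± 0.56 in LN). Their adjusted p were 0.776 and 0.774 by the edgeR quasi-likelihood test with Benjamini-Hochberg correction, so a change was not found. Leaving out LN day 20 b (-0.0012) or TIL day 8 b (-0.11) turned the sign in B16, and leaving out LN day 12 b (-0.02) or TIL day 8 b (-0.03) turned it in MC38.

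CD4+Foxp3- cells had few counts at Foxp3. In B16 the peak at 7583914 to 7584371 changed by -3.20 ± 1.08 (adjusted p = 0.0283 by edgeR), but 1 library, LN day 20 b, held 512 counts there (281 CPM), and TIL day 20 a held 45 (28.5 CPM). Without LN day 20 b the difference was 0.29 (adjusted p = 0.760), and the call also ended without TIL day 8 b (0.0602) or TIL day 20 b (0.141), so no change of this peak is claimed. A second B16 peak at 7587649 to 7587776 changed by -2.70 ± 0.55 (adjusted p = 2.06e-05). In MC38 the peak at 7583984 to 7584131 held 34 counts over the TIL libraries and 3 over the LN libraries, a ratio per depth of 10.9 (95% counting interval 3.41 to 55.3). Its call (adjusted p = 0.0401 by edgeR) turned to -1.76 under loess scaling and ended without LN day 12 a (0.0533), LN day 16 a (0.0730), LN day 16 b (0.136), LN day 20 a (0.105), LN day 20 b (0.0616), TIL day 16 b (0.221) or TIL day 20 b (0.154). A second MC38 peak at 7587645 to 7587782 changed by -1.57 ± 0.52 (adjusted p = 0.0164).

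**Figure D3:**
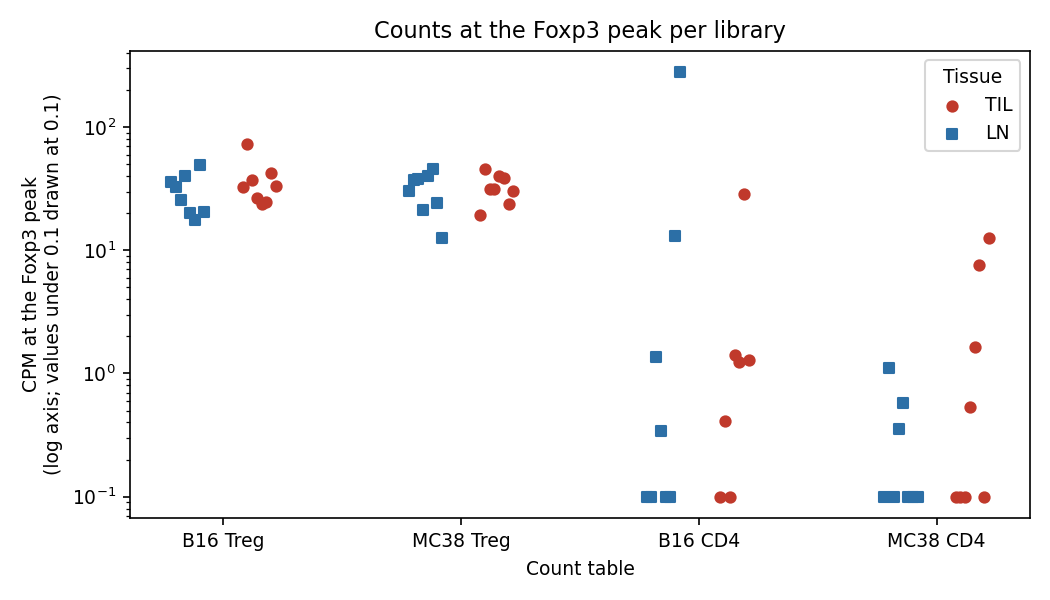
CPM of each library at the Foxp3 peak of each table. Each dot is 1 library.

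Markers of other cell types served to ask whether other cells could have entered the samples. In B16 CD4+Foxp3- cells the endothelial list closed (1 opened and 9 closed of 12 peaks, 1 and 10 over the list alone, adjusted p = 0.00375 by camera with the preset correlation), and adjusted p = 0.0408 with an estimated correlation, a call kept in 6 of 15 fits that each left out 1 library. Its gene Cdh5, which encodes VE-cadherin, changed by -1.98 ± 0.18 with 7 of 7 peaks closed. The B cell list closed as well (0 opened and 3 closed of 3 peaks, 0 and 3, adjusted p = 0.0422), and its gene Ebf1 changed by -2.60 ± 0.30. The B cell call was lost: adjusted p = 0.159 with an estimated correlation. It also ended without LN day 8 b, LN day 12 a or LN day 20 a, where its adjusted p reached 0.0527. CD8 and NK (3 opened and 9 closed, 3 and 9 over the list alone, adjusted p = 0.0993) and myeloid genes (3 opened and 4 closed, 3 and 4 over the list alone, adjusted p = 0.618) were not called in these cells. Nor were melanocyte (0 opened and 4 closed, 0 and 4 over the list alone, adjusted p = 0.157) and epithelial genes (2 opened and 8 closed, 2 and 8 over the list alone, adjusted p = 0.157).

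In B16 Treg no list of another cell type was called with all libraries. These were B cell (1 opened and 4 closed, 1 and 4 over the list alone, adjusted p = 0.265) and CD8 and NK genes (3 opened and 4 closed, 3 and 4 over the list alone, adjusted p = 0.636), myeloid (5 opened and 0 closed, 5 and 0 over the list alone, adjusted p = 0.0512) and melanocyte genes (2 opened and 4 closed, 2 and 4 over the list alone, adjusted p = 0.501). The last were epithelial (2 opened and 4 closed, 2 and 4 over the list alone, adjusted p = 0.627, median 0.17 and mean -0.41) and endothelial genes (4 opened and 2 closed, 4 and 2 over the list alone, adjusted p = 0.588). The myeloid list opened without LN day 8 b (0.0497), 12 a (0.0484), 12 b (0.0444), 16 b (0.0250) or 20 a (0.0496) or TIL day 8 a (0.0485), 16 a (0.0451) or 20 b (0.0486) or with loess scaling (0.0427), and in none of these fits with an estimated correlation (0.283 or more). In MC38 Treg no list of another cell type was called. These were B cell (1 opened and 3 closed, 1 and 3 over the list alone, adjusted p = 0.124) and CD8 and NK genes (2 opened and 4 closed, 2 and 4 over the list alone, adjusted p = 0.718), myeloid (3 opened and 2 closed, 3 and 2 over the list alone, adjusted p = 0.582) and melanocyte genes (3 opened and 4 closed, 3 and 5 over the list alone, adjusted p = 0.582). The last were epithelial (2 opened and 4 closed, 2 and 4 over the list alone, adjusted p = 0.537) and endothelial genes (4 opened and 3 closed, 5 and 3 over the list alone, adjusted p = 0.718). With all libraries none was called in MC38 CD4+Foxp3- cells: not B cell (0 opened and 3 closed, 0 and 3 over the list alone, adjusted p = 0.179), CD8 and NK (3 opened and 5 closed, 3 and 5 over the list alone, adjusted p = 0.446, median -0.12 and mean 0.16) or myeloid genes (3 opened and 2 closed, 3 and 2 over the list alone, adjusted p = 0.925). Nor were melanocyte (2 opened and 3 closed, 2 and 3 over the list alone, adjusted p = 0.155), epithelial (1 opened and 6 closed, 1 and 6 over the list alone, adjusted p = 0.0795) and endothelial genes (0 opened and 6 closed, 0 and 6 over the list alone, adjusted p = 0.105). Without TIL day 8 b the epithelial and endothelial lists closed (adjusted p = 0.0446 each, but adjusted p = 0.282 and 0.344 with an estimated correlation). Single peaks of Cdh5 (-1.26 ± 0.20) and Ebf1 (-1.21 ± 0.23) closed. The fibroblast list had too few tested peaks (under 3) in every table.

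A further comparison asks which changes the 2 tumors and the 2 cell types share, by matching each peak to the peak of the other table that it overlaps best. By the peak of lowest p of each gene, Il10, Klrg1, Il1rl1, Tbx21 and Ccl5 opened, and Satb1, Dapl1 and Tox closed, in each of the 4 tables. These peaks were chosen in each table by itself, without matching, and need not be the same site. In B16 and MC38 CD4+Foxp3- cells they start at 130993687 and 131022621 for Il10 and at 6970428 and 6901380 for Tox. For Klrg1 they overlap, starting at 122270228 and 122270209. Another Il1rl1 peak (chromosome 1, from 40399701 in the B16 Treg table), chosen after its values were seen, closed in Treg and opened in CD4+Foxp3- cells: -1.61 and 2.52 in B16, -1.01 and 2.05 in MC38. Of 41090 peaks matched between the Treg tables, 7300 opened in both tumors where chance gives 2297 (odds ratio 36.8), 7766 closed in both where chance gives 2430 (65.4), and 14 went opposite ways. Of 43995 peaks matched between CD4+Foxp3- cells, 7528 opened in both tumors (chance 2354, odds ratio 37.5), 7947 closed in both (chance 2430, odds ratio 65.2) and 9 went opposite ways. The Spearman correlation of log2 changes was 0.896 for Treg and 0.881 for CD4+Foxp3- cells.

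Within 1 tumor, the odds ratios between Treg and CD4+Foxp3- cells were lower. In B16, 6407 of 37246 matched peaks opened in both cell types (chance 2430, odds ratio 19.3), 6434 closed in both (chance 2170, odds ratio 33.7) and the correlation was 0.793. In MC38, 5541 of 39848 opened in both (chance 1707, odds ratio 23), 5266 closed in both (chance 1451, odds ratio 36.0) and the correlation was 0.806. The B16 peaks that closed in Treg and opened in CD4+Foxp3- cells numbered 324, and 33 went the other way. The MC38 counts were 75 and 8. The tables share no libraries and were normalized apart, so whether the tumor effect differs between the cell types was not tested.

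To ask whether the TIL to LN difference is present from the start, the 2 TIL and 2 LN libraries of each day were also compared. The spread was estimated over all days of a table, so a library far from its pair adds to the spread at every day. At days 8, 12, 16 and 20 the edgeR test called 11287, 10270, 4886 and 9981 peaks in B16 Treg. In B16 CD4+Foxp3- cells, whose day 12 has only 1 TIL library, it called 14977, 7600, 6000 and 10952. MC38 Treg had 0 at day 8 by edgeR (5192 at an unadjusted p under 0.05), then 1781, 9360 and 1222. MC38 CD4+Foxp3- cells had 2, 195, 10525 and 3200. In MC38, 1 of the 2 TIL libraries at days 8 and 12 lay near LN on the first component, so the low counts there do not show that the difference was absent.

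**Figure D4:**
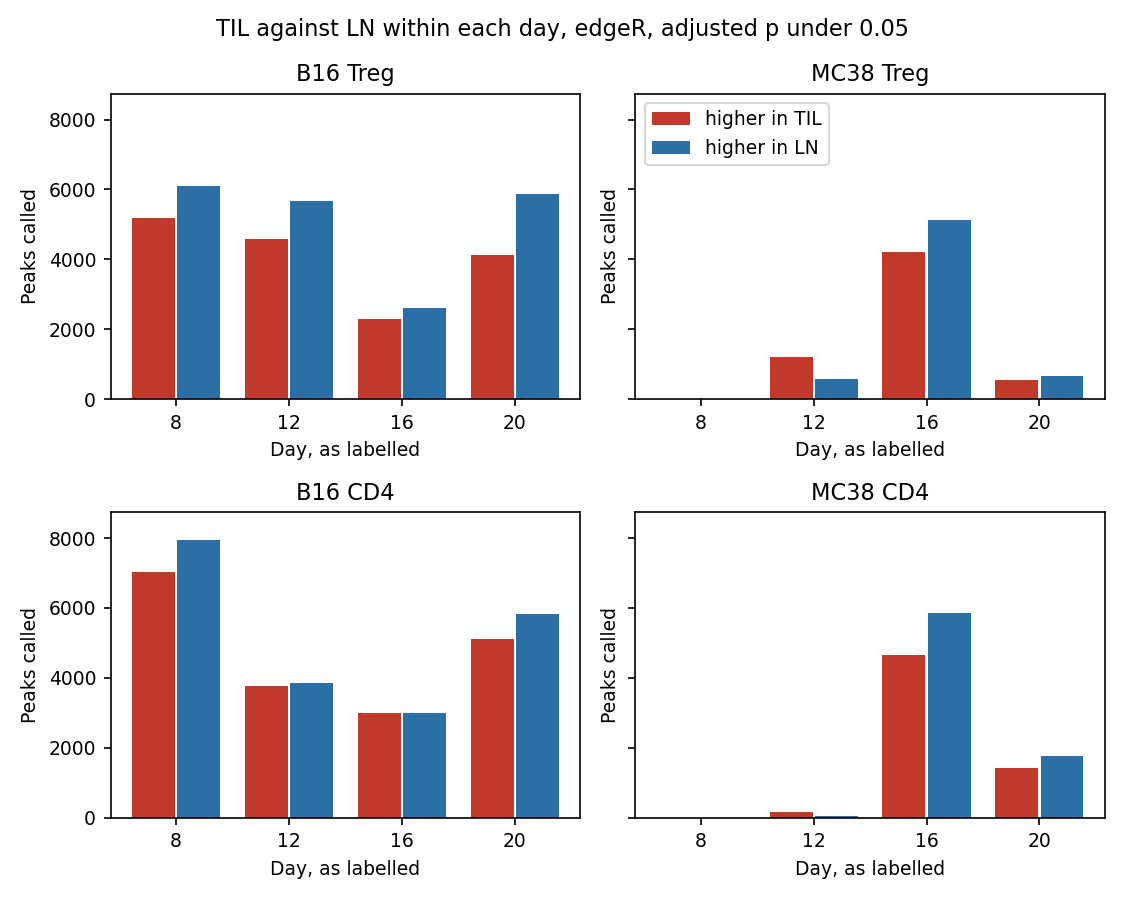
Peaks called between TIL and LN within each day in the 4 tables (edgeR quasi-likelihood test, adjusted p under 0.05).

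The day comparisons ask whether accessibility changes as B16 tumors grow (2 libraries per day). The day 16 libraries of both tissues held few counts in peaks. Totals were 550363 and 809101 in Treg LN and 900673 and 1089756 in Treg TIL. In CD4+Foxp3- cells they were 900735 and 816957 in LN and 747809 and 849218 in TIL. These libraries also lay highest on the second principal component, at 44.3 to 94.2 in Treg and 27.6 to 83.7 in CD4+Foxp3- cells. Depth or a batch at day 16 was not told apart from a change with day. In B16 Treg TIL, Lilrb4a, which encodes an inhibitory receptor, differed among days (adjusted p = 1.04e-05, edgeR quasi-likelihood F test over days, Benjamini-Hochberg), with a log2 difference of 2.71 for day 20 minus day 8. The F test asks for any difference among the 4 days, so the day 20 minus day 8 values given below were not tested by themselves. They were 1.75 at Scaf8, 1.64 at Sfi1, 1.81 at the formyl peptide receptor gene Fpr2 and 1.88 at the mineralocorticoid receptor gene Nr3c2. Mthfd1, a folate enzyme gene, had -2.07, Btbd9 -0.79 and Angptl2 -1.47. Whether reads at these or other peaks named for days could map to many places was not tested. Another Sfi1 peak, from 3101248 on chromosome 11, was high only in MC38 Treg LN day 20 b. That library had 15.5% of its counts on unplaced scaffolds. Of the list genes, a peak 3388 bp from Il7r, the IL-7 receptor gene, differed among days (2.42, adjusted p = 7.37e-05, edgeR). The calls of Areg and Tbx21 rest on single libraries: Areg had 1.37 (adjusted p = 0.00825, but 0.0631 without TIL day 8 b and 0.149 without TIL day 16 b). Tbx21 had -1.12 (0.0126, but 0.264, 0.094 and 0.0761 without TIL day 8 a, 16 a and 16 b).

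In all, 662 peaks differed among days in B16 Treg TIL by edgeR, with day 20 minus day 8 above 0 at 409 and below 0 at 253. An unadjusted p under 0.05 was reached at 6120. DESeq2 called 89 in TIL (81 above 0 and 8 below) and 225 in LN. It gave no adjusted p to 21491 peaks in TIL and 32667 in LN, which count as not called. Loess scaling gave 449 above 0 and 594 below. The count was 194 without TIL day 8 a, 169 without TIL day 8 b, 298 without TIL day 16 a, 132 without TIL day 16 b, 423 without TIL day 20 b, 998 without LN day 12 a and 1010 without LN day 12 b. In LN, 921 peaks of Treg differed among days (263 above 0, 658 below). Among them were Col19a1 (1.55), Scaf8 (1.29, not called with the share of counts on unplaced scaffolds as a covariate), Pdxp (-0.45), Yif1a (-0.60), the polarity kinase gene Mark2 (-0.30) and Tnrc6b (-0.19). That count was 338 without LN day 8 a, 127 without LN day 8 b, 1390 without LN day 12 a, 182 without LN day 16 a and 185 without LN day 16 b. The tissue by day interaction, which tests whether differences among days are unlike in TIL and LN, called 0 peaks by edgeR and 0 by DESeq2 (1630 at an unadjusted p under 0.05 by edgeR), and 4, 1 and 3 peaks without LN day 20 a, TIL day 8 a or TIL day 12 a. So the day changes of Treg in the tumor are not shown to differ from those in a distant LN.

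In B16 CD4+Foxp3- TIL, Pid1 differed among days by edgeR (0.81 for day 20 minus day 8), but DESeq2 did not call it. Nwd1 (3.48), the vacuolar sorting gene Vps45 (1.80) and the ubiquitin ligase gene Mid1 (2.04) did too, but their adjusted p became 0.368, 0.539 and 0.0727 by edgeR without TIL day 20 b. In LN, peaks at Zc3h7a (1.27 for day 20 minus day 8), Tmem267 (3.27) and Arhgap21 (2.59) differed among days. So did peaks at the mitochondrial leucyl-tRNA synthetase gene Lars2 (1.74) and the adenylate cyclase gene Adcy9 (2.74, not called by DESeq2). Others lay at Trappc2l (-0.37) and Pou2f1, which encodes Oct-1 (-0.22), where no fall is claimed. Peaks called by edgeR numbered 64 in TIL (day 20 minus day 8 above 0 at 59 and below at 5, 4341 at an unadjusted p under 0.05) and 490 in LN (237 above 0, 253 below). DESeq2 called 7 in TIL and 95 in LN (77 above 0 and 18 below). It gave no adjusted p to 46032 of 49465 peaks in TIL and 29729 in LN. A peak without one counts as not called, so a missing DESeq2 call need not be a failed test. The LN split was 261 and 179 with DESeq2 size factors and 244 and 130 with loess scaling.

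Both CD4+Foxp3- counts depended on single B16 libraries. The TIL count of 64 was 26 without TIL day 8 a, 546 without TIL day 8 b (281 above 0 and 265 below, so the balance of directions rests on that library), 25 without TIL day 16 a, 250 without TIL day 20 a and 10 without TIL day 20 b. It was 117, 116, 131 and 142 without LN day 8 a, 8 b, 12 a and 12 b, and 17 without LN day 16 a or 16 b. The LN count of 490 was 234 without LN day 8 a, 812 without LN day 12 a, 278 without LN day 12 b, 236 and 234 without LN day 16 a and 16 b, 228 and 271 without LN day 20 a and 20 b, and 894 and 885 without TIL day 8 a and 8 b. The interaction called 1 peak by edgeR, at Zc3h7a (chromosome 16, 11143905 to 11144315, -1.26, adjusted p = 0.0306), and 0 by DESeq2. It was 0 without LN day 8 a, 8 b, 12 b, 16 a, 16 b, 20 a or 20 b or TIL day 16 a, 16 b or 20 a, 3 without TIL day 8 a and 14 without TIL day 20 b.

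The same question about days in MC38 gave few called peaks. With a library left out, its tissue and day keep a single library, whose spread is taken from the other groups. Without TIL day 12 a, that library is TIL day 12 b, which lay near LN in both cell types. In Treg TIL 8 differed, all with day 20 minus day 8 above 0 (2091 at an unadjusted p under 0.05, 27 called by DESeq2, 22 above 0 and 5 below), among them a peak within the phosphatase gene Ptprm (0.75, adjusted p = 0.0218 by edgeR). The Ptprm call ended without TIL day 16 a (0.108), TIL day 16 b (0.136), TIL day 20 a (0.118), TIL day 20 b (1), LN day 8 b (0.0523), LN day 12 b (0.0517), LN day 16 a (0.0581) and LN day 16 b (0.0567). The count of 8 was 2, 1 and 3 without LN day 8 a, 8 b and 12 a, 0 without LN day 12 b, 16 a or 16 b or TIL day 16 a, 16 b, 20 a or 20 b, 24 without LN day 20 a, 3 without TIL day 8 a, 82 without TIL day 12 b (53 above 0 and 29 below) and 1807 without TIL day 12 a (898 above 0 and 908 below), so the single direction does not hold. In Treg LN edgeR called 0 peaks (1700 at an unadjusted p under 0.05, 221 called by DESeq2), 615 without LN day 20 a, and 35 and 33 without TIL day 12 a and 12 b. The interaction called 0 by edgeR (1282 at an unadjusted p under 0.05, 0 by DESeq2) and 88 without TIL day 12 a.

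CD4+Foxp3- cells of MC38 TIL had 0 peaks called among days by edgeR (3737 at an unadjusted p under 0.05, 3 by DESeq2), 1 without LN day 20 a or 20 b, 124 without TIL day 8 a and 1753 without TIL day 12 a. In LN 6 peaks differed, all with day 20 minus day 8 below 0, among them one at Stt3b, a glycosylation enzyme gene (-0.74, adjusted p = 0.034 by edgeR). Its adjusted p was 0.108, 0.763, 0.377, 0.284, 0.156 and 0.0506 without LN day 8 a, 8 b, 12 a, 12 b, 16 b and TIL day 16 a. The LN count was 0 without LN day 8 a, 8 b, 12 a, 12 b or 16 b, 3 without LN day 16 a or TIL day 16 a, 39 without LN day 20 a (33 above 0 and 6 below), and 16 without LN day 20 b, TIL day 12 a or TIL day 12 b. The interaction called 0 (2301 at an unadjusted p under 0.05, 0 by DESeq2), 6 without TIL day 8 a and 37 without TIL day 12 a.

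Lists tested over days were called only with camera's preset correlation, and each call ended without some single library. In B16 Treg TIL the core Treg list rose toward day 20 (adjusted p = 0.04, up to 0.583 without LN day 16 a, 16 b, 20 a or 20 b or TIL day 8 b or 20 a), and the tissue repair list rose (0.00236, up to 0.204 without TIL day 8 b or 20 a). Their adjusted p = 0.706 and 0.510 with an estimated correlation. In MC38 Treg TIL the effector and tissue repair lists rose (both 0.00536, 0.457 without TIL day 8 b) and the naive list fell (0.00136, 0.786 without TIL day 8 b), with adjusted p = 0.610 for all 3 with an estimated correlation. In MC38 Treg LN the tissue repair list rose (0.0124, up to 0.905 without LN day 8 a or 20 b), with adjusted p = 0.796 with an estimated correlation.

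In B16 CD4+Foxp3- LN, 4 lists rose toward day 20: effector (adjusted p = 0.0356, up to 0.253 without LN day 8 a, 16 a, 16 b, 20 a or 20 b), inhibitory receptors (0.0365, up to 0.564 without the same 5 libraries), naive genes (0.0319, up to 0.737 without LN day 8 b, 20 a or 20 b) and type 1 genes (0.0356, up to 0.354 without LN day 8 b, 16 a, 16 b, 20 a or 20 b). By camera, adjusted p = 0.565 for inhibitory receptors and 0.573 for the other 3 with an estimated correlation. In MC38 CD4+Foxp3- TIL the core Treg (0.026, up to 0.508 without TIL day 8 b or 20 b), effector (1.12e-06, 0.0764 without TIL day 8 b), type 1 (0.00286, 0.0648 without TIL day 20 a) and interferon lists (0.026, up to 0.422 without TIL day 8 b or 20 a) rose. All 4 had adjusted p = 0.357 with an estimated correlation.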

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

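Of the tests below, those of a swap, of early tumor growth, of Treg cells in the sort, of reads that map to many places, of library quality and of the splits were chosen only after the result was seen. A test for 1 library far from the rest of its group of 7 or 8 was made in 48 groups, and chance flags about 1 in 20 groups. It found 10 values. CPM at the Foxp3 peak was 73.1 in B16 Treg TIL day 8 b (next 42.7), 28.5 in B16 CD4+Foxp3- TIL day 20 a (next 1.41) and 281 in B16 CD4+Foxp3- LN day 20 b (next 13.2). MC38 Treg LN day 20 b stood apart by 15.5% of counts on unplaced scaffolds (next 3.75%), by 8.56% of counts in its 10 highest peaks (next 4.53%) and by 175 on the second principal component (next 1.42). B16 CD4+Foxp3- LN day 20 a had 9.12% of counts on unplaced scaffolds (next 5.84%). B16 CD4+Foxp3- TIL day 16 a lay at 64.5 on the first component (next 105). MC38 CD4+Foxp3- TIL day 20 b had 6.42% of counts in its 10 highest peaks (next 4.02%), and MC38 CD4+Foxp3- LN day 20 b lay at 185 on the second component (next -16.1). The Zc3h7a peak in B16 CD4+Foxp3- cells is listed because the tissue by day interaction was tested and called there (-1.26, adjusted p = 0.0306), a call that leaving out any of 10 libraries ended.

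TIL day 8 b and TIL day 12 b of MC38 lay near the LN libraries in both cell types, at 0.374 and 0.243 in Treg and 0.244 and 0.233 in CD4+Foxp3- cells on a scale from LN (0) to TIL (1). An effect of early tumor growth shared by all libraries of those days is argued against, since the other TIL libraries lay at 1.14 or above. The TIL end of the scale is the mean of the other TIL libraries, those near LN included, which lowers it. Each of these days has only 1 other TIL library, so variation among early tumors stays open. A mixed sample may be the source: positions read from opened and from closed peaks differed by up to 0.242, between the bounds of 0.2 and 0.3 set for and against it, so it stays open. A swap with an LN library is not decided by its bound, which was set to 0.5 in place of 0.25 after the value was seen. The highest LN library lay at 0.401 (MC38 Treg LN day 20 b), over the first bound. The partner in a swap would lie with the other TIL libraries, and no LN library lay at the 1.14 or above of those of days 8 and 12. A single wrong label or a swap with an outside sample was not tested. No biological explanation from the design other than the day was tested.

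The Foxp3 peak of B16 CD4+Foxp3- LN day 20 b held 281 CPM, 3.84 times the highest Treg library. Treg cells in the sort are argued against as the whole source. The 101 peaks far more open in Treg than in CD4+Foxp3- LN libraries (by 3 log2 or more) were raised in this library by a median of 0.301 log2. Its 95% interval was 0.111 to 0.494, under the bound of 0.5. Over all matched peaks the median was 0.053, below this interval, so a small share of Treg cells is not excluded. The threshold was raised from 2, where 636 peaks gave a median of 0.233, after part of those values had been seen. Reads that map to many places are argued against, as they would reach the other tumor's libraries, where the highest of 16 MC38 CD4+Foxp3- libraries held 12.5 CPM at a shorter peak within this one, far under 281. Extra DNA of this site alone, such as an amplified product, is a candidate explanation, as the nearest tested peaks were raised by at most 0.698 log2, under the bound of 1; no biological explanation was tested.

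B16 libraries differed among days in LN as well as in TIL. With the share of counts on unplaced scaffolds as a covariate, 61.0% of Treg calls in LN stayed called with the same sign of day 20 minus day 8 (63 more with the other), over the bound of 50%, which argues against library quality as the whole cause there. In CD4+Foxp3- cells 43.5% stayed with the same sign in LN (80 more with the other) and 9.38% in TIL, and as calls ended the median absolute change between days 8 and 20 (± median SE) shrank from 1.46 ± 0.35 to 0.80 ± 0.45 and from 1.22 ± 0.38 to 0.78 ± 0.45, so library quality may explain those calls. In Treg TIL 23.4% stayed, but that change barely moved where calls ended (0.97 ± 0.35 to 0.90 ± 0.35; 0.53 ± 0.29 to 0.38 ± 0.32 in Treg LN), so the lost calls speak neither for library quality nor against it. A batch shared by the libraries of a day may also take part: of the peaks called in LN, 81.0% in Treg and 63.3% in CD4+Foxp3- cells had the same sign in TIL, where no link gives 50%, over 80% in both would fit and under 60% in both would exclude it, while of those called in TIL 83.4% and 95.3% had the same sign in LN and 111 and 27 were called in both tissues (chance 13.8 and 0.634); day and batch cannot be told apart in this design, and tumor growth acting on both tissues stays open, untested apart from these.

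Of 21 splits of each table's libraries, only the real one called peaks between TIL and LN. It called 23242 in B16 Treg, 21322 in MC38 Treg, 26044 in B16 CD4+Foxp3- and 19785 in MC38 CD4+Foxp3- cells, and the highest of the others 0. This argues against a chance labelling only to 1 in 21, the lowest share these splits can give. The other splits mixed TIL and LN libraries in both groups, which adds the tissue difference to their spread. Splits also cannot show whether the libraries are independent.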

How the results depend on the processing

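Chosen only after the result was seen were the scaffold share as a covariate, MC38 without TIL day 8 b and TIL day 12 b, list peaks within 1 kb of a gene end, and leaving out libraries with the peaks held fixed. The other alternatives were planned. The count of peaks that differ between TIL and LN moved by over 1.5 times in 1 of the alternatives run, B16 Treg with no filter (42399). Without TIL day 8 b and TIL day 12 b it was 25989 in MC38 Treg and 24409 in MC38 CD4+Foxp3- cells. With each library left out and the peaks held fixed it ran from 21508 to 23031 in B16 Treg, 17630 to 23981 in MC38 Treg, 23768 to 26159 in B16 CD4+Foxp3- and 16556 to 22237 in MC38 CD4+Foxp3- cells. As first run, with the filter applied anew, it ran from 24704 to 28217, 18299 to 25980, 22033 to 26770 and 17232 to 23738.

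Counts among days depended on the setting. With DESeq2, B16 Treg had 89 in TIL and 225 in LN, MC38 Treg 27 and 221, B16 CD4+Foxp3- cells 7 and 95 with 0 for the interaction, and MC38 CD4+Foxp3- cells 3 and 24. Peaks to which DESeq2 gave no adjusted p count as not called there, up to 46032 of 49465 in B16 CD4+Foxp3- TIL. With no filter, B16 Treg had 1425 in TIL, 1775 in LN and 19 for the interaction, B16 CD4+Foxp3- cells 118 in TIL and 3 for the interaction, and MC38 CD4+Foxp3- cells 11 and 25. Loess scaling gave 1043 in B16 Treg TIL and 1 in MC38 CD4+Foxp3- TIL, and DESeq2 size factors in edgeR gave 3 in MC38 CD4+Foxp3- LN. With the scaffold share as a covariate, B16 Treg had 195 in TIL and 1 for the interaction, MC38 Treg TIL 0, and B16 CD4+Foxp3- cells 12 in TIL and 0 for the interaction. Without TIL day 8 b and TIL day 12 b, MC38 Treg had 57 in TIL and 57 in LN and MC38 CD4+Foxp3- LN 26. Leaving out 1 library with the filter applied anew or the peaks fixed gave, for TIL, LN and interaction, 132 to 1141, 127 to 1593 and 0 to 8 in B16 Treg, 0 to 2014, 0 to 626 and 0 to 215 in MC38 Treg, 10 to 567, 228 to 939 and 0 to 17 in B16 CD4+Foxp3- cells, and 0 to 2038, 0 to 43 and 0 to 64 in MC38 CD4+Foxp3- cells. The cause was not tested.

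The number of lists called between TIL and LN was 0 in B16 Treg, 0 in MC38 Treg, 2 in B16 CD4+Foxp3- and 0 in MC38 CD4+Foxp3- cells with an estimated correlation. It was 5 in B16 Treg with loess scaling, 2 in B16 CD4+Foxp3- cells with peaks within 1 kb of a gene end, and in MC38 CD4+Foxp3- cells 5 with no filter and 6 without TIL day 8 b and TIL day 12 b. Leaving out 1 library gave 3 to 5 in B16 Treg, 4 to 4 in MC38 Treg, 5 to 7 in B16 CD4+Foxp3- and 2 to 7 in MC38 CD4+Foxp3- cells. With an absolute log2 fold of 1 or more, 3369 opened and 4276 closed peaks were shared between tumors in Treg, 3477 and 4331 in CD4+Foxp3- cells, and 2344 and 3208 were shared between cell types in B16, 2081 and 2347 in MC38. A reciprocal overlap of 50% left all 8 shared counts within 1.5 times.

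Of 155 named TIL to LN peaks, 151 kept their call and direction in every alternative checked. The other 4 are Foxp3 peaks. Peaks chosen after their values were seen are not among the 155. The Foxp3 difference was -0.029 in MC38 Treg with loess scaling, -0.090 without TIL day 8 b and TIL day 12 b, and -0.029 to 0.19 with 1 library left out. It was -0.11 to 0.26 in B16 Treg and -5.24 to 0.29 in B16 CD4+Foxp3- cells with 1 library left out, and -1.76 at the first MC38 CD4+Foxp3- peak with loess scaling. Of 31 peaks named for days, 20 kept their call in every alternative checked, 11 lost it in some alternative and none turned. A peak to which DESeq2 gave no adjusted p was taken as not called. Of all 607 peaks that the naming rule allows, at most 486 kept their call and 30 turned in some alternative. Among fits with 1 library left out, only those of lowest and highest log2 difference were checked for these totals. For named peaks, every such fit was also checked with the peaks held fixed. No paired analysis was possible because the column names carry no replicate numbers of the sample labels, if pairs are to follow those numbers. The planned replicate block was therefore not run. In most column names the serial numbers run in sets that hold both tissues and both cell types of a day. A block by these sets was an option that was not tested. The labels do not say what the serial numbers stand for, so whether a set shares an animal is unknown. Promoter peaks (no strand), a background matched for length and GC content (no genome) and every alternative of the 2 further tables were not run.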

Other observations

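Between TIL and LN the list of core genes of the Treg lineage was not called in either Treg table, except lower with peaks within 1 kb of a gene end (adjusted p = 0.0276 in B16 and 0.0202 in MC38, but adjusted p = 0.168 and 0.399 with an estimated correlation). At Ctla4, which encodes an inhibitory receptor, B16 Treg had 5 opened and 5 closed of 17 tested peaks, and the peak of lowest p changed by -2.97 ± 0.24. In MC38 Treg 3 opened and 4 closed, with the strongest peak opened (1.12 ± 0.22). At Il2ra, the gene of CD25, 8 of 15 peaks closed in B16 Treg (-2.27 ± 0.28) and 1 opened, while MC38 Treg had 4 opened and 3 closed. Ikzf2, which encodes Helios, gained peaks in both (12 opened and 5 closed in B16, 12 and 1 in MC38). Whether the tumors differ at these genes was not tested.

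Tcf7, the gene of TCF-1, was mixed in CD4+Foxp3- cells. It had 5 opened and 5 closed peaks in B16 and 7 opened and 1 closed of 21 in MC38, while B16 Treg had 0 opened and 7 closed of 13 and MC38 Treg 2 and 5 of 14. Whether the cell types differ at Tcf7 was not tested. A peak within Camk2d, chosen after its values were seen (chromosome 3, from 126825035 in the Treg table), closed in Treg and opened in CD4+Foxp3- cells in both tumors: -3.13 and 2.85 in B16, -1.72 and 2.61 in MC38. Camk2d encodes a calcium-dependent kinase. At a peak near Akap6, also chosen after its values were seen, B16 Treg changed by -2.12 and B16 CD4+Foxp3- cells by 2.19. No alternative was checked for the Camk2d and Akap6 peaks.

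Some peaks are high in 1 library only, with at least 40 counts and over 5 times the next. B16 Treg TIL day 12 b has 14 such peaks, among them one at Pgk1 with 1249 counts (679 CPM, next 120), MC38 Treg LN day 20 b has 11 and B16 CD4+Foxp3- LN day 20 b has 1, the Foxp3 peak. Replicate pairs spread more than counting alone gives, with a chi-square per degree of freedom of 1.29 to 8.49.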
